A study of Homo sapiens with 24 samples.

How the data were processed

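The data were 24 eCLIP libraries of HEK293 cells, input and immunoprecipitate (IP) with 2 labelled replicates each, for 6 experiments: SNRNP200 in whole cells and in the cytoplasmic fraction, each untreated and with 500 µM arsenic, CAPRIN and G3BP1. Replicates were grouped by protein, fraction, treatment and library type as the labels give them, which makes 12 groups of 2. The time of treatment is not given in the sources used here. The treatment field of the labels names arsenic for all samples, while their characteristics give no treatment for the untreated ones, and the characteristics were used. By these the CAPRIN and G3BP1 samples were untreated. The protocols of all samples name the same antibody number although 3 proteins were immunoprecipitated, and the protein named in each label was used.

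Per the submitters' processing notes, the authors trimmed reads with fastp 0.11.5 and aligned them with STAR 2.7.6 to hg38. The program that called the windows is not given in the sources used here. The authors deposited 6 lists without column names, so the columns were identified from their values. The deposited read counts per window are raw counts of input and of IP, each summed over the replicates by the authors. The deposited log2 values are the enrichment of IP over input relative to windows of the same GC class, with the lowest, the mean and the highest replicate. The deposited p values and q values are the highest and lowest over the replicates, and the authors kept windows with q under 0.2. The deposited GC content is a fraction of the bases of the window. The deposited number of replicates in which a window was called enriched is 2 throughout, except for 654 G3BP1 windows with 3. With 2 replicates the lowest and the highest value are both replicates, but without their numbers. The mean was checked to be the midpoint of both in every such window, and the log2 values were checked to rise with the log2 ratio of the counts within a GC class with slopes of 0.925 to 0.994.

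The G3BP1 list holds 3242 entries in 2 sets told apart by their GC classes, 1254 with up to 2 replicates and 1988 with up to 3, with 219 windows in both and 2 empty lines. Windows of both sets were used for feature types and genes, and the set with up to 2 replicates for differences in enrichment. Library totals were not used here, and the counts in listed windows are not a depth, so no share was computed against a library total. Intervals cover counting error only, and reads of neighbouring windows are not independent. Windows of several genes were counted for each of them. Gene symbols are those of the lists, and no genome sequence was used here.

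The comparisons, the gene lists, the tests and the rule for named genes were chosen before the data were examined. They were whole cell arsenic against untreated, cytoplasmic arsenic against untreated, cytoplasmic against whole cell without and with arsenic, CAPRIN against G3BP1, and the difference of the arsenic effect between fractions. A gene counted as found with at least 1 window. Genes shared by 2 lists were tested with Fisher's exact test, two-sided, over the 9792 genes with a window in any list. Feature types were tested with Fisher's exact test between lists of windows, with p adjusted by Benjamini and Hochberg within each comparison. These tests compare lists and not replicates, so they do not measure the spread between samples.

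Differences in enrichment were tested per gene in 1 representative window, the shared window with the highest IP count, on the 2 replicate values of each list. The test was limma 3.58.1 in R 4.3.3 (moderated, two-sided, unpaired, not centred), with adjusted p under 0.05. The authors normalised each list on its own, so differences of level between lists include differences of their baselines. With 2 samples against 2, an exact permutation test could not reach 0.05. Tested on simulated data with planted differences of log2 1, 2, 3 and 5, limma recovered 0%, 2%, 18% and 84% in whole cells, 0%, 0%, 9.09% and 36.4% in the cytoplasm, 10%, 50%, 100% and 100% between fractions without arsenic, 0%, 0%, 3.85% and 53.8% with it, and 5.26%, 38.9%, 100% and 100% between CAPRIN and G3BP1.

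The 22 gene lists were U1, U2, U4, U5, U6 and minor spliceosome snRNA, snoRNA and scaRNA, 7SK, 7SL, Y, vault and RNase P or MRP RNA, the mitochondrial genome, replication-dependent histones, cytosolic ribosomal proteins, nuclear-retained long noncoding RNA, stress granule proteins, long stress granule RNAs, heat shock and oxidative stress response, spliceosome proteins, SR and hnRNP proteins, translation factors, oxidative phosphorylation, proteasome, cell cycle and mitosis, and the immunoprecipitated proteins. Lists with at least 3 members among the 9792 genes were tested in each experiment with Fisher's exact test, and against 10000 random lists matched on the number of windows. The U4 list had 1 member and was not tested. Lists with at least 5 representative windows were tested between conditions by a two-sided permutation test of their median with 10000 random lists. Adjustment was over all lists and experiments or comparisons. In a further test, chosen after the membership counts were seen, the members found in only 1 of 2 lists were compared with the other genes found in only 1 (Fisher's exact test, adjusted over 60 tests). On simulated lists without a shift, the permutation test gave p under 0.05 in 4.5% to 6.5%, and 95% intervals of odds ratios held the planted value in 93% to 96%. The simulated lists were random genes, so they do not cover lists whose genes vary together. Such a correlation could not be estimated, and the permutation p-values treat genes as independent.

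Named genes were, per comparison, the 10 with the largest difference in each direction among those past the test with replicate ranges that did not overlap, filled up with others said not to pass. They also included the 5 genes with most windows among those found in 1 list only, the 10 genes with the highest enrichment in windows with at least 50 IP reads, and up to 4 members per gene list. Fewer are named where none passed the test.

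Alternatives tried were centring, a variance trend with mean enrichment, the mean over windows, q under 0.05, at least 20 IP and 10 input reads, 1 window per gene, lists of equal length, weighting by IP counts, identical or overlapping windows, and a background of protein-coding genes. Chosen after seeing the data were the removal of windows above 64-fold enrichment, the G3BP1 sets taken singly or with 3 replicates, and for 5′ UTRs the removal of ribosomal protein genes, classes of GC and a minimum of 10 input reads. Odds ratios over 10 GC classes were combined by Mantel and Haenszel, and a median of count ratios used a pseudocount of 0.5 and 2000 bootstrap draws. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.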

Results

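Binding of 3 proteins to RNA was mapped by eCLIP in HEK293, a line of human embryonic kidney cells. In eCLIP, a protein crosslinked to RNA is immunoprecipitated (IP), and the reads along transcripts are set against those of an input library from the same lysate. SNRNP200 is the helicase of the U5 snRNP that unwinds the paired U4 and U6 RNAs in the spliceosome. CAPRIN1 and G3BP1 bind each other and are core proteins of stress granules, the assemblies of mRNA and protein that form when translation initiation is blocked. The label of the CAPRIN libraries does not give the family member. The 24 libraries fall into 12 groups of 2, input and IP for each of 6 experiments: SNRNP200 from whole cells, untreated or with 500 µM arsenic, SNRNP200 from the cytoplasmic fraction, untreated or with arsenic, CAPRIN, and G3BP1. By the characteristics of their samples, CAPRIN and G3BP1 were mapped without arsenic. The labels do not say whether the 2 replicates were separate cultures, so the limma p-values below measure only the spread between the deposited samples. Those of Fisher's exact test and of the permutation tests compare windows or genes and do not measure that spread.

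The authors deposited 1 list of reproducibly enriched windows per experiment, each window at most 100 bases long on hg38. The whole cell lists held 182066 windows in 9052 genes without arsenic and 117690 windows in 8202 genes with it. The cytoplasmic lists held 4182 windows in 1818 genes and 6773 windows in 2472 genes. The CAPRIN list held 15831 windows in 4363 genes, and the G3BP1 list held 3023 windows in 1232 genes. Library totals are not in the lists, so the depth of each sample is unknown. Summed over both replicates, the IP reads in listed windows numbered 8092831 and 5567969 for the whole cell experiments, 189220 and 358572 for the cytoplasmic ones, 635845 for CAPRIN and 218234 for G3BP1, which counts the 219 windows in both of its sets 1 time for each. The median window had 28, 29, 30, 32, 20 and 23 IP reads in the same order. The median replicate range of a window, its highest minus its lowest log2 enrichment, was 0.81, 0.86, 0.75, 1.02 and 0.46 for the SNRNP200 and CAPRIN lists in that order. It was 0.64 in the G3BP1 windows with 2 replicates.

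**Figure D1:**
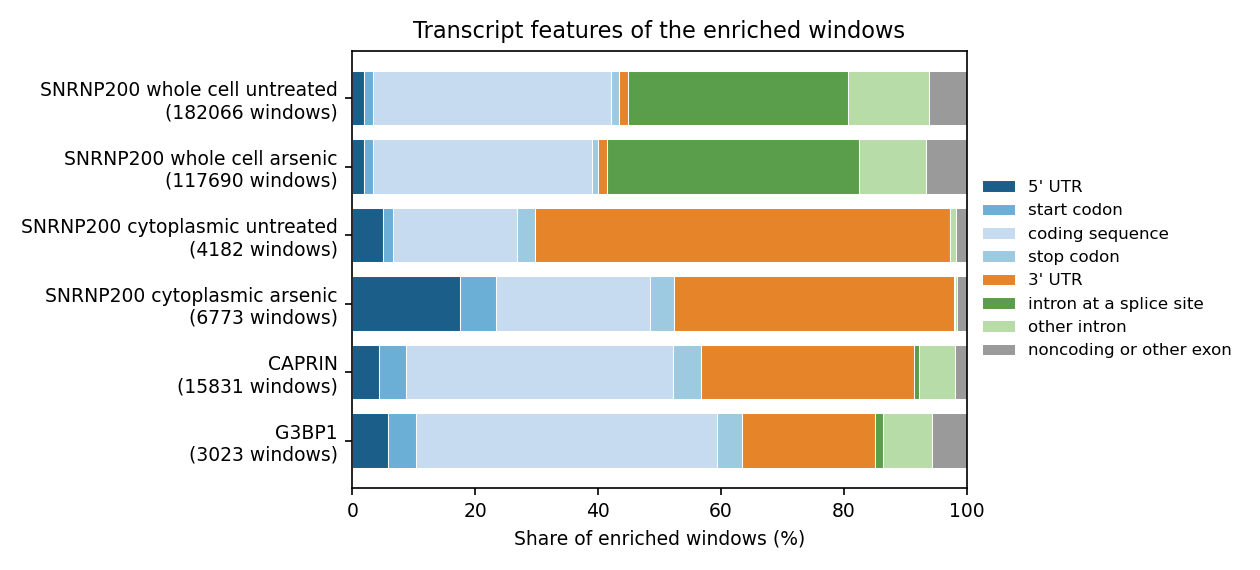
Share of enriched windows (x axis, percent) in each type of transcript feature for the 6 deposited lists (y axis). Introns at a splice site made up 35.7% and 41.0% of the whole cell SNRNP200 windows, and 3′ UTRs made up 67.6% and 45.5% of the cytoplasmic ones.

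The first comparison, SNRNP200 in whole cells with and without arsenic, asks how the stress changes the RNAs that a spliceosomal helicase contacts. Introns at a 5′ splice site held 21.3% of the windows with arsenic (25112 of 117690) and 18.3% without (33371 of 182066). Introns at a 3′ splice site held 17% and 14.8%. Coding sequence held 35.7% and 38.7%, and introns near but not at a splice site held 8.85% and 10.9%. Each of these 4 differences passed Fisher's exact test between the lists of windows, the largest adjusted p being 5.7e-57 for 3′ splice sites. The difference of 3.01 percentage points at 5′ splice sites was 0.776 with lists of equal length (Fisher's exact test, p = 3.8e-06), 1.83 weighted by IP counts and -0.637 with 1 window per gene (p = 0.37). That of -3.02 points in coding sequence was -7.50 with q under 0.05, and with 1 window per gene it no longer passed (-1.30 points, p = 0.0613, Fisher's exact test). The 3′ UTR share was 1.48% with arsenic and 1.59% without, and this small difference changed sign under every alternative tried.

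Genes named for U6, the snRNA that SNRNP200 helps to free from U4, numbered 28 with a window in any of the 6 lists. Of these 28, 27 had a window in whole cells with arsenic and 14 without. Totals of the other snRNAs were counted in the same way, so none is the number of copies in the genome. All 13 U6 genes found in only 1 of the whole cell lists were in the arsenic list, against 214 other genes found only with arsenic and 1077 found only without (Fisher's exact test, adjusted p = 2.0e-09). This test of genes found in only 1 of 2 lists, here and below, was chosen after the numbers of members listed were seen. U2 genes had a window in 14 and 11 of 15, U5 genes in 5 and 4 of 5, and the 3 genes of the minor spliceosome in 3 and 3. U1 genes had one in 1 and 1 of 6, and a single U4 copy, RNU4-78P, was listed with arsenic. In the authors' deposited table, the strongest windows were RNU6-1266P at log2 7.50 with arsenic (replicates 6.15 and 8.84), RNU2-63P at 5.36 (5.19 and 5.53) and RNU5E-10P at 6.25 (6.12 and 6.38), on 1, 0 and 5 input reads. Small RNAs took 4.75% of the IP reads in listed windows with arsenic and 3.82% without. Copies of an snRNA can be alike in sequence, so the copy a read comes from, and with it the number of copies, is uncertain. The symbols of the copies named here end in P, the ending given to pseudogenes. Whether the other listed copies are functional genes was not examined.

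Stress genes were among those found only with arsenic. Of the 227 genes found only there, those with most windows were MT1X with 16, PRDM10 with 11, MT2A with 9, MAPK8IP1 with 8 and ARG2 with 7. MT1X and MT2A encode metallothioneins, which bind metals, and the authors' deposited table put their strongest windows at log2 6.49 (5.51 and 7.47) and 6.44 (5.40 and 7.48). Of the heat shock and oxidative stress genes, 5 were found only with arsenic and 2 only without, against 222 and 1075 other genes (Fisher's exact test, adjusted p = 0.011). A gene can be listed only where its RNA is present, and amounts of RNA were not compared. Genes found only with arsenic need therefore not be newly bound. The 1077 genes found only without arsenic were led by PEX10, a peroxisome assembly factor, with 18 windows, GPAM with 16, and NIPSNAP1, PIGQ and RGS16 with 15 each. Both lists held 7975 genes, 97.2% of those with arsenic (odds ratio 16.7, 95% interval 14.1 to 19.8). They shared 91143 windows, 77.4% of those with arsenic.

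In the windows of both lists, no gene passed: limma called 0 of 7408 representative windows (284 had an unadjusted p under 0.05). The largest differences were in LYST, a regulator of lysosome traffic, at 3.77 (SE 1.06) and in NCDN at -3.38 (SE 0.86), both with limma adjusted p = 0.99. LMO4 at 3.48, CCDC134 at 3.45 and SUGP1, a splicing factor, at 3.41 were likewise higher in both replicates, and MTFMT at -3.23, TRIOBP at -3.14 and TENT4A at -3.14 lower, without passing. The replicate ranges did not overlap in 2376 of them, where chance gives 33.3% for 2 samples against 2. Simulated differences of log2 3 were recovered in 18% of windows and those of log2 5 in 84%, so smaller changes were not detectable. None of the 14 fixed gene lists with enough windows differed from the other genes in its median difference (smallest permutation p = 0.0251, adjusted p = 0.41, for the 32 heat shock and oxidative stress genes at a median of 0.53 against 0.10 for all).

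The second comparison sets SNRNP200 in the cytoplasm with arsenic against the cytoplasm without it. With arsenic, 5′ UTRs held 17.5% of the windows (1184 of 6773) and without it 4.95% (207 of 4182), an odds ratio of 4.07 (95% interval 3.49 to 4.74). Windows at a start codon held 5.91% and 1.58%, coding sequence 25.1% and 20.3%, and 3′ UTRs 45.5% and 67.6%. All 4 differences passed Fisher's exact test between the lists of windows, the weakest in coding sequence at an adjusted p of 2.1e-08. The windows of the arsenic list were richer in input reads, with a median of 14 against 3, and in GC, with a median fraction of 0.531 against 0.465. In windows with at least 10 input reads compared within 10 classes of GC, the odds ratio for 5′ UTRs was 1.01 (0.766 to 1.33).

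Relative to the other genes, 3 gene lists were over-represented among the genes found only with arsenic. Of the cytosolic ribosomal protein genes, 51 were found only with arsenic and 1 only without, against 1313 and 709 other genes (odds ratio 27.5, adjusted p = 1.6e-07, Fisher's exact test). For oxidative phosphorylation genes the numbers were 47 and 1 (odds ratio 25.3, adjusted p = 5.5e-07), and for replication-dependent histone genes 26 and 0 (adjusted p = 0.000159). Proteasome genes, with 18 and 2, and translation factors, with 12 and 1, did not pass (adjusted p = 0.106 and 0.145, Fisher's exact test). Ribosomal protein genes thus had a window in 72 of 83 with arsenic and 22 of 83 without, and oxidative phosphorylation genes in 53 and 7 of 90. Histone genes had one in 38 and 12 of 53, proteasome genes in 23 and 7 of 43, and translation factors in 31 and 20 of 44. In the authors' deposited table the strongest of these windows with arsenic included RPL8 at log2 5.05 (4.35 and 5.75), H3C1 at 6.65 (5.65 and 7.65), CYC1 of respiratory complex III at 6.08 (3.73 and 8.42) and PABPC1, the poly(A)-binding protein, at 7.09 (4.74 and 9.44). The larger number of input reads with arsenic stands beside these gene counts as well. The baselines differed too: a listed log2 of 0 corresponded to 9.15 input reads per IP read with arsenic and 1.03 without. How far this changed which genes were listed was not tested.

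Of the 1364 genes found only with arsenic, SLC1A5, a glutamine transporter, had the most windows with 21. PRKCSH and RHOA followed with 15 each, then RPL8 and YWHAZ with 13 each. The 710 genes found only without arsenic were led by JUN, a transcription factor of the stress response, with 16 windows, 8 of them in its 3′ UTR, and MCL1, which blocks apoptosis, with 13. SEC16A and URB2 with 10 each and MSH6, a mismatch repair protein, with 9 came next. Both lists held 1108 genes, 60.9% of those without arsenic (odds ratio 7.56, 95% interval 6.77 to 8.45), but shared 1065 windows, 25.5% of those without arsenic.

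In the shared windows the deposited enrichment was higher with arsenic almost throughout. Its median difference over the 1065 shared windows was 2.00, and 96.5% of them were higher. In 481 of the 669 representative windows the replicate ranges did not overlap, where chance gives 33.3%, and 474 of these were higher with arsenic. MANF, a factor of the unfolded protein response, in its 3′ UTR on chromosome 3 at 51389167 to 51389243, differed by 5.67 (SE 1.19), PABPC1 by 5.19 (SE 1.44), KPNA2, a nuclear import receptor, by 5.15 (SE 1.20) and PPIA, a prolyl isomerase, by 4.72 (SE 1.21). Limma called 0 of the 669 (196 had an unadjusted p under 0.05, and the adjusted p of these 4 was 0.13). With a variance that follows mean enrichment limma called 112, all higher, with the mean of windows 30, with q under 0.05 19 of 38, with at least 20 IP and 10 input reads 62 of 283, and after removal of the median difference 0 (20 at an unadjusted p under 0.05). Each list was normalised on its own by the authors, so a difference of level between them includes a difference of baseline: a listed log2 of 0 corresponded to 9.15 input reads per IP read with arsenic and 1.03 without.

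**Figure D2:**
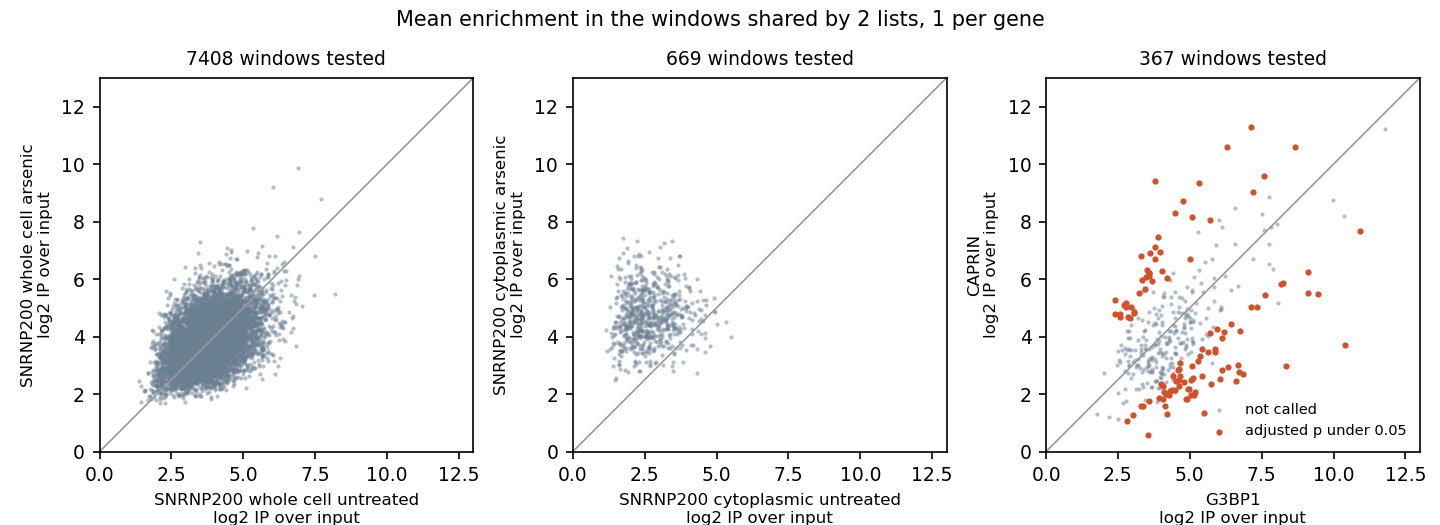
Mean deposited log2 enrichment of IP over input in the windows shared by 2 lists, with 1 representative window per gene. Each point is the mean of 2 replicates, the line marks equal values and red points passed limma. In the cytoplasm most of the 669 points lie above the line, and between CAPRIN and G3BP1 111 of the 367 points passed.

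The third comparison, cytoplasm against whole cell for SNRNP200, asks how the windows of the cytoplasmic fraction differ from those of whole cells. Introns at a splice site held 64983 of 182066 whole cell windows (35.7%) and 3 of 4182 cytoplasmic ones (0.0717%) without arsenic. With arsenic they held 48205 of 117690 (41.0%) and 9 of 6773 (0.133%, 95% exact interval 0.0608 to 0.252). The 3′ UTR share was 67.6% in the cytoplasm and 1.59% in whole cells without arsenic (odds ratio 129, 95% interval 119 to 138), and 45.5% and 1.48% with it (odds ratio 55.7, 52.1 to 59.6). Coding sequence was less frequent in the cytoplasm in both cases, at 20.3% against 38.7% and 25.1% against 35.7%. With lists of equal length the difference without arsenic was -7.05 points in place of -18.4, and that with arsenic was -1.23 points in place of -10.6 and did not pass (p = 0.107, Fisher's exact test).

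Nearly all genes of the cytoplasmic lists were in the whole cell lists too: 1711 of 1818 (94.1%) without arsenic and 2244 of 2472 (90.8%) with it. The odds ratios were 1.38 (1.12 to 1.70, p = 0.00267, Fisher's exact test) and 2.25 (1.94 to 2.61). The first did not pass among protein-coding genes (1.06, p = 0.651, Fisher's exact test). At the level of windows, 651 (15.6%) and 882 (13%) of the cytoplasmic ones were shared. NORAD, a cytoplasmic noncoding RNA that binds Pumilio proteins, had 28 and 20 cytoplasmic windows, all in exons, and none in whole cells. KCTD12, with 15 and 12, and SOX4, a transcription factor, with 9 and 11, were also absent from the whole cell lists, as were RBM15B with 12 and EXOSC6 with 9 without arsenic, and GAS1 and H1-10 with 8 each with it. Of the windows without arsenic, 10 of 15 in KCTD12 and 7 of 9 in SOX4 lay in 3′ UTRs. Whether these genes have introns, where many whole cell windows lay, was not examined. Their absence from the whole cell lists therefore does not place their contacts in the cytoplasm alone. Of the genes with whole cell windows and no cytoplasmic one, UBR4 had 335 and 286, MDN1, a ribosome assembly factor, 234 and 218, and POLE, a DNA polymerase, 212 and 160. NBPF20 had 213 and 158, NBPF19 had 183 without arsenic and MYCBP2 had 194 with it.

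Histone genes stood out among the genes found in only 1 of the fractions, again without regard to their introns. With arsenic 30 were found only in the cytoplasm and 3 only in whole cells, against 198 and 5955 other genes (Fisher's exact test, adjusted p = 4.3e-39). Without arsenic the numbers were 4 and 14, against 103 and 7327 (adjusted p = 0.000576, Fisher's exact test). Genes of snoRNA and scaRNA, with 6 and 1, and genes of the mitochondrial genome, with 5 and 0, also leaned to the cytoplasm with arsenic (adjusted p = 1.6e-07 and 5.5e-07, Fisher's exact test). Without arsenic, relative to the other genes, so did heat shock and oxidative stress genes, with 3 and 15, and long stress granule RNAs, with 2 and 8 (adjusted p = 0.0101 and 0.0366, Fisher's exact test). With arsenic, a listed log2 of 0 corresponded to 9.15 input reads per IP read in the cytoplasm and 1.62 in whole cells. Cytoplasmic small RNA windows with arsenic ran from 20 IP and 38 input reads in SCARNA14 to 24 and 12 in SCARNA6. Whether the baseline decided which genes were listed was not tested.

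Limma called 0 of 390 shared windows without arsenic (65 at an unadjusted p under 0.05) and 0 of 527 with it (94 at an unadjusted p under 0.05). With at least 20 IP and 10 input reads it called 3 higher and 15 lower of 96 without arsenic and 1 higher of 313 with it. With arsenic it also called 3 higher with a variance trend and 1 with q under 0.05. The lists were normalised separately, and the median difference over all tested windows was 0.12 and 1.31. As a group, the 16 ribosomal protein windows without arsenic had a median difference of -1.03, against 0.12 for all windows (permutation p = 0.0004, adjusted p = 0.0098), and 1 of the 16 was above 0. Against lists matched on enrichment the adjusted p was 0.0049, and with q under 0.05 fewer than 5 of these windows were left and the list was not tested. RPL3 differed by -2.07 (SE 0.64) and RPL7A by -2.02 (SE 0.60). No member passed alone, also not adjusted over the list alone. Among the other genes, NSD1, a histone methyltransferase, differed by 2.82 (SE 0.57) and RBBP6 by 2.82 (SE 0.57) and SNHG20 by -2.88 (SE 0.62), all with limma adjusted p = 0.259. With arsenic, PTMA, or prothymosin alpha, differed by 4.11 (SE 1.05), HSP90AB1, a chaperone, by 3.37 (SE 1.08) and SNRNP70, the U1 protein, by -1.81 (SE 0.85), with limma adjusted p = 0.257, 0.257 and 0.259. Of 97 windows present in all 4 lists, 68 were representative and tested for an arsenic effect that differed between fractions. Limma's interaction test called 0 of these 68 (21 at an unadjusted p under 0.05). It called 2 with at least 20 IP and 10 input reads, and 2 without windows above 64-fold. In a simulation with 13 changed windows, spread over differences of log2 1, 2, 3 and 5, this test recovered 0% at log2 5. That share rests on few windows.

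The fourth comparison sets CAPRIN against G3BP1, 2 partners in stress granules, both mapped in cells without arsenic. Both lists held 952 genes, 77.3% of the G3BP1 genes and 21.8% of the CAPRIN genes (odds ratio 5.13, 95% interval 4.46 to 5.90). They shared 1688 windows, 55.8% of the G3BP1 windows. The 3′ UTR share was 34.8% for CAPRIN and 21.6% for G3BP1 (odds ratio 1.93, 1.76 to 2.12), small RNAs held 0.316% and 2.02%, and exons of long noncoding RNAs 0.556% and 2.71%. The G3BP1 list joins 2 sets of windows, 1254 called with up to 2 replicates and 1988 with up to 3, although the labels give 2 replicates. Against the first set alone the 3′ UTR difference turned from 13.1 to -9.42 percentage points, and against the second it was 27.8, so no direction for 3′ UTRs holds for both.

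Replication-dependent histone mRNAs, which end in a stem-loop in place of a poly(A) tail, were listed for nearly all members: 49 of 53 genes for CAPRIN and 46 of 53 for G3BP1, against 44.3% and 12.2% of other genes (Fisher's exact test, adjusted p = 2.0e-12 and 1.5e-32). Only 7 representative histone windows were shared with the G3BP1 set of up to 2 replicates, and the other histone genes were not tested for enrichment. In these 7 windows enrichment was higher for CAPRIN. All 7 passed limma as higher, 7 also adjusted over the list alone. Their median was 3.10 against -0.47 for all windows (permutation p = 0.0001, the smallest possible with 10000 random lists, adjusted p = 0.0049). Against lists matched on enrichment the adjusted p was 0.0588, and with q under 0.05 fewer than 5 histone windows were left and the list was not tested. All 7 windows were above 64-fold enrichment in at least 1 of the lists. H2BC21, on chromosome 1 at 149886165 to 149886259, was higher by 5.64 (SE 0.53, adjusted p = 0.00093), H4C3 by 3.93 (SE 0.51, adjusted p = 0.00323) and H2AC4 by 3.27 (SE 0.59, adjusted p = 0.00819). Among genes found in only 1 of the lists, where 3411 were in that of CAPRIN and 280 in that of G3BP1, histone genes numbered 6 and 3 and did not pass (odds ratio 0.163, adjusted p = 0.0965, Fisher's exact test). Of the snoRNA and scaRNA genes found in only 1 list, 18 were in that of G3BP1 and 4 in that of CAPRIN, and of 7SK, 7SL and similar RNAs 12 and 7 (adjusted p = 6.8e-16 and 1.4e-08, Fisher's exact test). U1 genes were found in 5 of 6 for G3BP1 and in 0 of 6 for CAPRIN (adjusted p = 1.6e-05, Fisher's exact test).

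Limma was run on the G3BP1 set with up to 2 replicates and called 41 of the 367 representative windows higher for CAPRIN and 70 lower. Without windows above 64-fold enrichment it called 12 and 19 of 298, with q under 0.05 21 and 46 of 222, and with at least 20 IP and 10 input reads 5 and 16 of 63. Of the 20 genes named as passing here and above, 19 had a window above 64-fold in at least 1 of the lists. Higher for CAPRIN were FTO, an RNA demethylase, by 4.29 (SE 0.74), CYTH1 by 4.16 (SE 0.60), TUBA1B, an alpha-tubulin, by 4.02 (SE 0.51), RNF139 by 3.82 (SE 0.56), FKBP4, an HSP90 co-chaperone, by 3.57 (SE 0.58), HNRNPH2 by 3.49 (SE 0.55) and ECHS1 by 3.31 (SE 0.57). Lower for CAPRIN were FBXO31, in an intron on chromosome 16 at 87383975 to 87384073, at -6.70 (SE 0.54), CENPB, a centromere protein, at -4.15 (SE 0.73), CELF1, a 3′ UTR binding protein, at -4.15 (SE 0.51), HSPA4, an HSP70 family chaperone, at -3.96 (SE 0.58), DIPK2A at -3.99 (SE 0.66), MRTO4 at -3.68 (SE 0.50) and ZNF275 at -3.58 (SE 0.68). So were AC084082.3 at -5.36 (SE 0.56), RN7SKP176 at -4.15 (SE 0.58) and LINC01783 at -3.50 (SE 0.53). The lists were normalised separately: after removal of the median difference of -0.41 the numbers were 50 higher and 36 lower, and in the G3BP1 windows called with 3 replicates they were 100 and 4 of 192. Whether more windows were higher or lower for CAPRIN therefore changed with the centring and with the set of G3BP1 windows.

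Among the ribosomal protein windows 4 of 14 passed limma, among those of SR and hnRNP proteins 5 of 17, among those of stress granule proteins 3 of 12, and 1 each of the 6 for translation factors and the 5 for the cell cycle. The same numbers passed adjusted over the list alone, and none of these lists differed as a group from the other genes (permutation adjusted p of 0.477 or more). Of the 3411 genes found only for CAPRIN, AMOT, an angiostatin-binding scaffold protein, had the most windows with 48, then IRS4, an insulin receptor substrate, with 38, HCFC1 with 37, INTS1 with 29 and DBN1 with 22. The 280 genes found only for G3BP1 were led by LINC01002 with 18 windows, CH507-513H4.6 with 9, CCDC200 with 8, and CTD-2515O10.6 and FAM157C with 7 each.

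**Figure D3:**
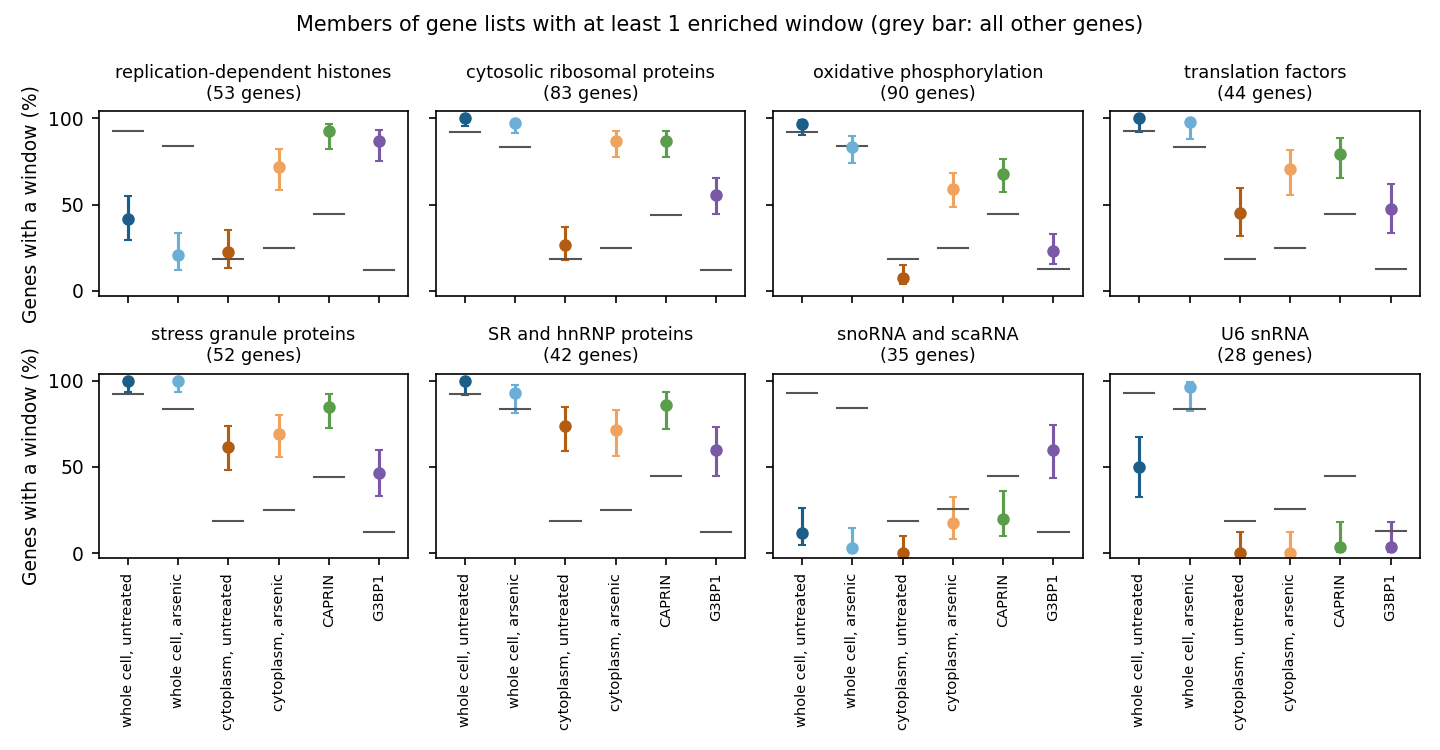
Percent of the genes of 8 fixed lists with at least 1 enriched window (y axis) in each of the 6 experiments (x axis). Points give the percent, bars its 95% Wilson interval, and grey lines the percent among all other genes. Histone genes are at 92.5% for CAPRIN and 86.8% for G3BP1, and ribosomal protein genes at 26.5% in the untreated and 86.7% in the arsenic-treated cytoplasm.

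Across the 6 experiments, 126 tests of the fixed lists asked whether their genes had a window more or less often than the other genes of the union of 9792. By Fisher's exact test 51 passed above and 22 below. Of the 73, 40 also passed, in the same direction, against random genes matched on their number of windows. Genes of stress granule proteins were above the rest in both cytoplasmic lists, with 32 and 36 of 52, and for CAPRIN and G3BP1, with 44 and 24. So were those of SR and hnRNP proteins, which bind pre-mRNA, with 31 and 30 of 42, and 36 and 25. Of the stress granule genes, PABPC1 led the CAPRIN and G3BP1 lists at log2 7.82 and 7.82 in the authors' deposited table (7.54 and 8.09, and 7.37 and 8.27), each time in its 5′ UTR. Histone genes were below the rest in whole cells, with 22 of 53 without arsenic and 11 with it. Genes of snoRNA and scaRNA were below it there too, with 4 and 1 of 35, and above it for G3BP1, with 21. The 24 genes of 7SK, 7SL and similar RNAs had 2 and 1 members listed in whole cells and 15 for G3BP1. Spliceosome protein genes were above the rest for CAPRIN, with 59 of 74, and so were cell cycle genes, with 42 of 46. The list named nuclear-retained long noncoding RNA had 7 and 7 of 7 members listed in whole cells. In the untreated cytoplasm it had 4 (adjusted p = 0.045, Fisher's exact test, and 0.0694 against lists matched on the number of windows). Where these RNAs lie in these cells was not examined, so the 4 do not show nuclear RNA in the cytoplasmic fraction. The mRNAs of the 3 immunoprecipitated proteins were all listed in 5 experiments, and 2 of 3 in the untreated cytoplasm, with no matched test passing. Mitochondrial genome transcripts had 2 and 0 of 8 members listed in whole cells. The lists are those of the authors and hold only windows that passed, so absence of a window is not absence of binding. Of the 60 tests of genes found in only 1 of 2 lists 14 passed. With q under 0.05 in place of 0.2, 11 of 56 passed. Only 6 of the 14 were among these in the same direction. These were U6 with arsenic in whole cells, ribosomal proteins with arsenic in the cytoplasm, heat shock and oxidative stress genes between the untreated fractions, histones between the fractions with arsenic, and, for G3BP1, snoRNA and scaRNA and the list of 7SK, 7SL and similar RNAs. Not passing were histones (adjusted p = 0.0554, Fisher's exact test) and oxidative phosphorylation (0.134) with arsenic in the cytoplasm, and histones (1) and long stress granule RNAs (0.206) between the untreated fractions. With fewer than 5 genes left, heat shock genes in whole cells, snoRNA and scaRNA and the mitochondrial genome between the fractions with arsenic, and U1 were not tested. Other lists passed only with q under 0.05. In the cytoplasm, heat shock, stress granule and SR and hnRNP genes leaned to the untreated list (adjusted p = 0.0102, 0.0128 and 0.0174, Fisher's exact test). Between the fractions with arsenic, oxidative phosphorylation genes leaned to the cytoplasm (adjusted p = 4.8e-05, Fisher's exact test).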

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

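The tests of the library baseline, of nuclear complexes and of signal common to several proteins were chosen after the results they concern were seen.

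The difference between the arsenic and untreated lists in types of transcript feature was not the same in the cytoplasm and in whole cells. The ratio of the odds ratios, cytoplasm over whole cell, was 4.02 (95% interval 3.42 to 4.73) for 5′ UTRs, 4.13 (3.15 to 5.41) for start codons, 1.5 (1.36 to 1.65) for coding sequence and 1.67 (1.32 to 2.10) for stop codons. It was 0.433 (0.392 to 0.479) for 3′ UTRs, 0.425 (0.243 to 0.743) for introns away from splice sites and 0.505 (0.343 to 0.743) for exons of long noncoding RNAs. These 7 stand here because that difference was itself tested between the fractions, over windows and not over replicates, and without regard to GC content and input reads, with which the cytoplasmic odds ratio for 5′ UTRs was 1.01. The 654 G3BP1 windows called in 3 replicates stand here because the labels give 2 replicates, and the test of enrichment leaves these windows out.

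The larger share of 5′ UTR windows in the arsenic-treated cytoplasm, such as those of PABPC1 and H3C1, had a crude odds ratio of 4.07. GC content alone was not the whole cause, since over 10 GC classes the odds ratio was 1.88 (1.59 to 2.24). Among windows with at least 10 input reads, 774 of 4182 without arsenic and 4872 of 6773 with it, it was 1.54 (1.20 to 1.97), which leaves the number of input reads open. Both together gave 1.01 (0.766 to 1.33), so GC content and input reads may account for the difference. An effect of arsenic on 5′ UTR contacts stays untested beyond this.

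The higher enrichment in the cytoplasm after arsenic, a median of 2.00 over the 1065 shared windows including MANF and KPNA2, was set against the baseline of the libraries. Without that baseline the ratio of IP to input reads in these windows changed by a median of -1.36 (-1.47 to -1.28), while the baseline moved by 3.35. The median input count of these windows was 18 with arsenic and 8 without, and IP counts were 42 and 48, so the baseline and an arsenic effect cannot be told apart. Introns at splice sites held 0.133% (exact interval 0.0608 to 0.252) of the cytoplasmic arsenic windows against 41.0% in whole cells. The median listed window had 14 input reads, against 3 in whole cells with arsenic. Windows with 0 input reads numbered 1 of 6773, against 12234 of 117690 in whole cells with arsenic. Splice-site windows with little input could thus be missed. The low share therefore holds for listed windows and does not exclude carry-over of nuclear SNRNP200 complexes at splice sites. U2, U5 and U6 genes had 0 of 15, 0 of 5 and 0 of 28 members listed, against 14, 5 and 27 in whole cells with arsenic. Nuclear RNA of other kinds stays open too, since 6 of 35 snoRNA and scaRNA genes were listed with arsenic and 0 without. Small RNAs took 5.93% of the IP reads in the arsenic list and 0.0174% in the untreated one, and 5.68% came from 1 window in the mitochondrial MT-RNR2. An effect of arsenic on SNRNP200 in the cytoplasm stays open.

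Windows above 64-fold enrichment recurred across proteins, as in SPIN4, PRKCA, ETV5 and CTC1. Of the 643 such CAPRIN windows, 24 (3.73%) were above 64-fold in an SNRNP200 list too, against 64 of the 15188 others (0.421%), an odds ratio of 9.16 (5.69 to 14.7). That odds ratio describes the recurrence and does not decide between explanations: signal common to unrelated immunoprecipitations, the single antibody number that the labels give for all 3 proteins and binding shared by the proteins all stay open. Binding of 1 stretch over neighbouring windows stays open too. These windows were more often the sole CAPRIN window of their gene, 120 of 643 (18.7%) against 1593 (10.5%), with an odds ratio of 1.96 (1.60 to 2.40). This was set beforehand as evidence against it, wrongly, because 523 of the 643 were not sole windows and 345 (53.7%) abutted another CAPRIN window, against 44.0% of the others. No biological explanation was tested.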

How the results depend on the processing

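Alternatives without windows above 64-fold, with single G3BP1 sets or 3 replicates, and those of the test of genes found in 1 of 2 lists were chosen after seeing the data. No paired analysis was possible because the columns do not give replicate numbers, and for the same reason no replicate could be left out in turn. The interaction had no windows left under q 0.05. Of the values that answer a comparison, 39 tested ones kept direction and side of the threshold, 29 moved, 3 reversed and 2 weakened. Another 17 values without a test of their own stayed within 1.5 times of the first value. Counts of 0 by limma stayed 0 in 55, which says little about stability where simulated differences were seldom recovered. For feature types, these numbers cover only the largest difference of each comparison and 5′ UTRs between the cytoplasmic lists. Among the other values, such as feature shares with smaller differences, 38 stayed the same, 10 moved, 9 reversed, 4 weakened and 1 strengthened. The cause was not tested, except where stated.

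Among protein-coding genes the odds ratio of genes shared between the untreated fractions was 1.06, and 7 of 46 tests of genes found in 1 of 2 lists passed. Noncoding lists drop out there by construction, which does not account for every call lost. With an identical window required, the odds ratios between fractions were 0.0210 and 0.0503, by construction, since few windows are shared. With 1 window per gene, arsenic changed whole cell shares by -1.30 points in coding sequence, -0.637 at 5′ splice sites and 0.152 in 3′ UTRs. The last was 0.155 with q under 0.05, 0.218 with lists of equal length and 0.0707 weighted by IP counts. Weighting by IP counts gave -3.91 points for coding sequence in whole cells, and for 3′ UTRs -31.5 between the cytoplasmic lists, 59.6 and 28.1 between fractions without and with arsenic, and 17.9 for CAPRIN against G3BP1. For this last pair coding sequence turned from -5.55 points to 8.11 with q under 0.05, 8.47 weighted and 31.2 with the G3BP1 set of up to 2 replicates, where 3′ UTRs were -9.42. With the set of up to 3, coding sequence was -25.9, and 5′ UTRs were 1.57 in place of -1.52.

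Matched on the number of windows, 46 of the 126 tests of gene lists in the experiments passed. Between conditions 1 list passed when matched on enrichment and 0 with q under 0.05, where the 2 lists that had passed, histones for CAPRIN against G3BP1 and ribosomal proteins between the untreated fractions, had too few windows to be tested. Limma called higher in the arsenic-treated cytoplasm 112 genes with a variance trend, 30 with the mean of windows, 19 with q under 0.05 and 62 with the count minimum. Between fractions the count minimum gave 3 higher and 15 lower without arsenic and 1 higher with it, where the trend gave 3 and q under 0.05 gave 1. For CAPRIN against G3BP1 the numbers higher were 21 with q under 0.05, 5 with the count minimum, 12 without windows above 64-fold and 100 with 3 replicates, and those lower 46, 16, 19 and 4, and 36 when centred. The interaction gave 2 higher with the count minimum and 2 without windows above 64-fold.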

Other observations

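Windows above 64-fold enrichment were a small part of most lists: 669 and 648 in whole cells without and with arsenic, 8 and 150 in the cytoplasm, 643 for CAPRIN and 146 for G3BP1. They held 22.4% of the IP reads of the CAPRIN list and 33.4% of those of the G3BP1 list, with windows in both G3BP1 sets counted 1 time. Of these windows 455, 395, 5, 4, 490 and 95, in the same order, had 0 or 1 input read, so many such log2 values rest on an almost empty input. In SPIN4, a gene of the spindlin family, the coding window on chromosome X at 63350536 to 63350627 stood at log2 13.02 for CAPRIN in the authors' deposited table (12.48 and 13.55), with 9.20 for SNRNP200 in whole cells with arsenic and 6.20 in the untreated cytoplasm. The window before it, at 63350445 to 63350535, stood at 11.54, 7.65 and 8.93 in the authors' deposited table. A window in PRKCA, a protein kinase C, stood at 12.93, 9.85 and 7.43 for the same experiments in the authors' deposited table. CTC1, a telomere protein, stood at 11.23 for CAPRIN and 11.78 for G3BP1 there. The window at log2 13.02 and that in PRKCA had 0 input reads for CAPRIN and in whole cells with arsenic, and that in CTC1 had 0 in both lists. Of such windows 50 were above 64-fold for 2 proteins and 0 for 3.

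The cytoplasmic SNRNP200 windows overlapped those of CAPRIN and of G3BP1, which were both mapped without arsenic. Identical windows in the CAPRIN list numbered 2399 with arsenic (35.4% of the SNRNP200 windows and 15.2% of the CAPRIN windows) and 1371 without (32.8% and 8.66%). In the G3BP1 list they numbered 751 with arsenic (11.1% of the SNRNP200 windows and 24.8% of the G3BP1 windows) and 418 without (10.0% and 13.8%). The whole cell SNRNP200 lists held 2582 of the CAPRIN windows with arsenic (16.3%) and 4426 without (28%), and 628 (20.8%) and 1041 (34.4%) of the G3BP1 windows. At the level of genes 75.3% and 73.3% of the cytoplasmic SNRNP200 genes were also in the CAPRIN list. The lists differ in length, 15831 windows for CAPRIN and 3023 for G3BP1, and the overlap of windows was not tested against the other fraction.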
